A study of Homo sapiens with 16 samples.

How the data were processed

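The series measured RNA turnover by SLAM-seq in THP-1 cells, a human monocytic leukaemia line, carrying either wild-type ALKBH5 or an ALKBH5 knockdown. SLAM-seq reads the incorporation of 4-thiouridine (4sU) into new RNA as T-to-C conversions in sequencing reads. Per the labels' protocols, cells received 100 µM 4sU for 1 h, were washed, and were then kept in 10 mM uridine, the chase, until collection at 0, 1.5, 4.5 or 7.5 h. Polyadenylated RNA was extracted with TRIzol and made into libraries with a NEBNext kit, per the labels' protocols. The labels gave 16 libraries in 8 groups, 2 replicates for each of 2 genotypes at each of 4 times. Nothing in the labels said that the replicates came from separate cultures, so p-values may measure technical spread between these libraries only.

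The deposited table held one value per gene and library, a fraction between 0 and 1, for 60564 genes. From the values and the assay this fraction was read as the T-to-C conversion rate, the converted bases as a share of the sequenced T bases of a gene, and is given here in percent. The file headers name neither the rate nor the tool that made it. Per the submitters' processing notes, CASAVA, HISAT2 2.1.0 and the hg38 build were used; how variants were masked and which annotation was used are not given in the sources used here. Columns beginning with S were taken as the knockdown by elimination, since those beginning with C carry the initial of the control. The table also holds a single CPM column, per the file headers, and a gene length. All CPM values under 1000 reads were whole reads within a tolerance of 0.1 at a step of 0.0265, for 37800087 reads in total, but the library they came from is not stated. Among 28329 genes with a CPM of 0, between 546 and 1895 had a rate above 0 in each library, so the column could not be matched to one. It served only as a measure of abundance, to filter, rank and match genes and to set the variance trend. The length column equalled the summed transcript spans, introns included, for 71.6% of 58457 genes matched to GENCODE 29, and was not used further.

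The number of T bases behind each rate is not in the table, so the depth per library and gene is unknown, and no counting interval or floor was given. A rate of 0 is called listed at 0. No library without 4sU was used here, so the background of sequencing mismatches in unlabelled RNA was not measured. A conversion rate is a share: it falls as labelled RNA is lost and as unlabelled RNA is made, and it carries no information on the abundance of a transcript.

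Because the values were rates and not counts, the count-based tests fixed for the design could not be applied and the fallback fixed beside them was used. Rates in percent plus a pseudocount of 0.05 percentage points were put on the log2 scale. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances following a trend in log2(CPM + 0.01) and Benjamini-Hochberg adjustment at 0.05. Genes with a CPM of at least 1 and a rate above 0 in any library were tested, 16241 in all. The genotype effect was knockdown minus control with time as a factor of 4 levels over all 16 libraries. The slopes came from a fit with an intercept and a slope per hour of chase for each genotype, and the slope difference was the knockdown slope minus the control slope. Effects at 0 h and 7.5 h came from a fit of 8 group means. No replicate block was used. The groups, comparisons, covariates, threshold, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. The pseudocount, the CPM minimum and the variance trend were set after the table was opened. A CPM minimum of 5 was tried first and replaced by 1 because it removed ALKBH5, the knockdown target, at a CPM of 4.55.

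The knockdown libraries had higher rates at every time. Each comparison was therefore also run with every library centred on its own median log2 rate, and these values are called centred. Centring took away a common shift of 1.05 log2 from the genotype effect of each gene, of −0.136 log2 per hour from the control slope and of −0.150 log2 per hour from the knockdown slope, so centred values are changes relative to those shifts.

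The text names ALKBH5, the genes of an axis list, the genes with the largest changes and up to 4 members per list with the smallest adjusted p. Genes with the largest changes were taken from those past the threshold and at or above the median CPM of 9.66. They were 10 per direction for the genotype effect, with the same direction at all 4 times, and 10 falling and 5 rising for each slope. A few genes that met these rules or the rule for closer study are not reported here, though they stayed in every test and count. For the slope difference, where none passed, the 3 with the smallest p in each direction were taken. The rule's abundance condition was applied to the CPM column, and which of the named list members appear was chosen after their values were seen. Symbols came from a table of gene names, which matched 60295 gene identifiers.

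The 27 gene lists were m6A machinery; KDM4C, MYB and TAM receptor axis; immediate early and short-lived mRNAs; glycolysis and cytoskeleton; translation elongation and initiation; cytoplasmic ribosomal proteins; mitochondrially encoded mRNAs; nuclear-encoded respiratory chain subunits; p53 targets; DNA replication and S phase; mitosis; replication-dependent histones; cholesterol biosynthesis. They further held interferon-stimulated genes, ATF4 and unfolded protein response, heat shock proteins, monocyte and macrophage differentiation, MLL-fusion and leukaemia stem cell programme, inflammatory cytokines and NF-kB targets, BCL2 family and cell death, and hypoxia targets. The remaining lists were snoRNA host genes and NMD-sensitive transcripts, nuclear and unstable long noncoding RNAs, zinc finger transcription factors, and markers of lymphoid, erythroid and megakaryocyte, and epithelial and embryonic kidney cells. The axis list was chosen from background knowledge of this study. The 25 lists with at least 5 tested members were tested with camera in limma on the test statistics, at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. None of these list tests used the variance trend of the gene tests. Camera ranks a list's statistics against those of all other genes, so under a common shift it favours lists of abundant, precisely measured genes.

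Coordinates are from GENCODE 29 on hg38, a copy that may differ from the annotation the authors used. Overlaps with other genes in this annotation are mentioned for some of the genes with the largest changes, not always by name. How reads were assigned to overlapping genes or strands is not given in the sources used here.

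The tests of the slope difference, the centred genotype effect and the control slope were run on simulated log2 rates. In each, 200 genes were changed by known amounts, and the other comparisons were not simulated. Noise was drawn from a normal distribution with the moderated variances of the data. Neither rates listed at 0 nor depth were simulated, so the shares below describe an ideal case. Among genes at or above the median CPM, a slope difference of 0.1, 0.2 or 0.4 log2 per hour was recovered in 2.99%, 25.4% and 74.2% of 67, 67 and 66 genes. A control slope of those sizes was recovered in 8.96%, 62.7% and 93.9%. A centred genotype effect of 0.5, 1 or 2 log2 was recovered in 28.4%, 77.6% and 100% of the genes. Of 71, 146 and 116 calls in the slope difference, centred genotype and control slope simulations, 3, 9 and 6 were false.

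Alternatives covered other pseudocounts, CPM minimums, the absence of the variance trend, centring, subtraction of a background, a replicate block, other forms of time, subsets of libraries and leaving out each library in turn. Motifs of the DRACH type, the sequence context of m6A, were counted in the transcript with the longest coding sequence per gene, and in 3′ UTRs of at least 100 bases.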

Results

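T-to-C conversion rates were compared between control and ALKBH5 knockdown THP-1 cells over a 7.5 h chase, to follow the loss of RNA labelled in a 1 h pulse. ALKBH5 removes m6A, a methyl mark on adenosine, from RNA. Each of the 8 groups held 2 libraries, and 16241 genes were tested. The mean of the library medians in control was 0.548% ± 0.0115 (SD, n = 2) at 0 h, 0.475% ± 0.00107 at 1.5 h, 0.319% ± 0.00865 at 4.5 h and 0.252% ± 0.00234 at 7.5 h. In knockdown it was 1.18% ± 0.00858, 1.09% ± 0.00212, 0.732% ± 0.00131 and 0.533% ± 0.000955 at the same times. The share of tested genes listed at 0 ranged from 2.39% to 12.9% per library. Spearman correlations between replicates, across genes that are not independent replicates, ran from 0.361 in control at 7.5 h to 0.740 in knockdown at 0 h. The depth behind each rate is unknown.

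**Figure D1:**
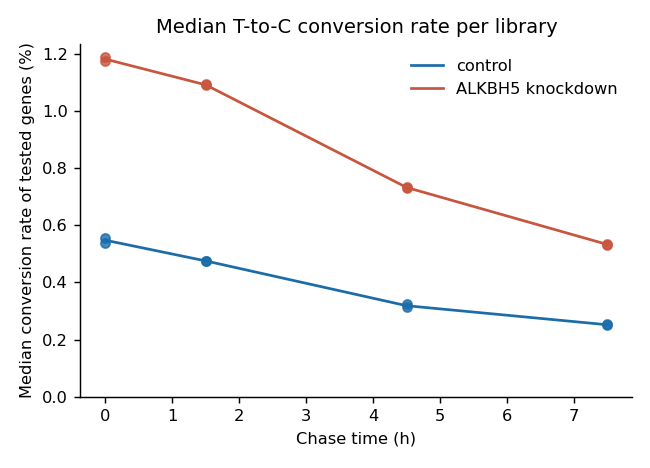
Median conversion rate of tested genes in percent (vertical axis) against chase time in hours (horizontal axis). Points are the 16 libraries and lines join the means of the 2 replicates; knockdown medians fell from 1.18% to 0.533% and control medians from 0.548% to 0.252%.

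ALKBH5, the targeted m6A demethylase, had a higher conversion rate in knockdown than in control at the start of the chase and a similar rate at its end. In control its rate was 0.812% and 0.386% in the 2 libraries at 0 h, 0.802% and 0.745% at 1.5 h, 0.304% and 0.410% at 4.5 h, and 0.0982% and 0.191% at 7.5 h. In knockdown it was 3.31% and 2.46% at 0 h, 2.08% and 1.46% at 1.5 h, 1.35% and 0.246% at 4.5 h, and 0.108% and 0.149% at 7.5 h. The gene (ENSG00000091542) lies on chromosome 17 from 18183078 to 18209954. Its genotype effect was 0.99 log2 (SE 0.369, limma adjusted p = 0.0269), about the median of all genes, and −0.06 when centred (adjusted p = 0.954). At 0 h the effect was 2.24 (SE 0.661, limma adjusted p = 0.0216) and at 7.5 h it was −0.09 (adjusted p = 0.943). These rates carry no abundance, so they do not test the knockdown itself.

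The ALKBH5 genotype call rested on single libraries. It ended without control 0 h replicate 2 (0.78, adjusted p = 0.0613), knockdown 0 h replicate 1 (0.84, 0.0620) or replicate 2 (0.91, 0.0540), knockdown 1.5 h replicate 1 (0.93, 0.0519) or knockdown 4.5 h replicate 1 (0.81, 0.0619). The 0 h call also ended without control 0 h replicate 2 or either knockdown 0 h library, over a range of 1.75 to 2.74.

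The first comparison asked how rates differed between genotypes over the whole chase. MYB, a haematopoietic transcription factor, was 1.52 log2 higher in knockdown (SE 0.124, n = 8 libraries per genotype). KDM4C, a histone demethylase, was 1.15 higher (SE 0.0997) and AXL, a receptor tyrosine kinase of the TAM family, was 1.22 higher (SE 0.0848). AXL rates at 0 h were 0.281% ± 0.00891 in control and 0.773% ± 0.0794 in knockdown (SD, n = 2). These differences lay within a broad shift, with 11297 genes higher, 28 lower and 4916 not past the threshold by limma, and a median of 1.02 log2, or 2.03-fold. After centring 236 genes were higher and 746 lower.

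Averaged over the 4 times, cholesterol biosynthesis genes stood above the common shift. At 0 h their median rate was 0.572% in control and 1.23% in knockdown, against 0.548% and 1.18% for all tested genes. This excess was thus not seen at the start of the chase. At 7.5 h the medians were 0.247% and 0.712%, against 0.252% and 0.533%. Of 23 tested members 21 were higher, and 22 adjusted over the list alone; their median was 1.36 log2, and 0.31 when centred. The centred camera test called this list (adjusted p = 0.00238; adjusted p = 0.0356 with an estimated correlation). SQLE, squalene epoxidase, was 1.45 higher (SE 0.0624; centred 0.40, adjusted p = 7.9e-04), FDPS, farnesyl diphosphate synthase, 1.34 (SE 0.143) and HMGCS1, which makes HMG-CoA, 1.29 (SE 0.138). SREBF2, the transcription factor that drives the pathway, was 1.00 higher (SE 0.103), which turned to −0.05 when centred. After centring 1 of the 23 members passed, and 1 adjusted over the list alone.

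Averaged over the 4 times, mitosis genes lay above the shift with the preset correlation but not with an estimated one. At 0 h their median rate was 0.613% in control and 1.32% in knockdown, against 0.548% and 1.18% for all tested genes. At 1.5 h the medians were 0.621% and 1.66%, against 0.475% and 1.09%. Of 38 tested members 37 were higher, and 38 adjusted over the list alone, with a centred median of 0.15; after centring 5 passed, also 5 adjusted over the list alone, and 33 did not. The centred camera test gave adjusted p = 0.00316, and adjusted p = 0.197 with an estimated correlation. PRC1, which bundles spindle microtubules, was 1.53 higher (SE 0.0774; centred 0.48, adjusted p = 0.00207). CCNB1, cyclin B1, was 1.52 higher (SE 0.0951), CENPF, a kinetochore protein, 1.43 (SE 0.0897) and NUSAP1, a spindle-associated protein, 1.16 (SE 0.0603).

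Several abundant transcripts were higher by less than the shift, so that their sign turned after centring. LYZ, lysozyme of monocytes, was 0.48 higher (SE 0.0358; centred −0.57, adjusted p = 8.7e-08). Its rate at 0 h was 0.0559% ± 0.0013 in control and 0.0911% ± 0.0016 in knockdown, close to the pseudocount. The pseudocount shrinks log2 differences at low rates, and centred effects were not run at another pseudocount. MALAT1, a nuclear long noncoding RNA, was 0.75 higher (centred −0.30, adjusted p = 8.6e-05), IFITM1, an interferon-induced membrane protein, 0.73 (centred −0.32), CCL5, a chemokine, 0.74 (centred −0.31) and TMSB4X, an actin-binding thymosin, 0.74 (centred −0.31). POLR2A, the largest RNA polymerase II subunit, did not pass at 0.28 (adjusted p = 0.132) and was lower when centred (−0.77, adjusted p = 0.0118). The histone H4C3 was 1.51 higher (centred 0.46, adjusted p = 4.9e-05).

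Within the axis list 5 of 7 tested genes were higher, and 5 adjusted over the list alone. After centring MYB was higher (0.47, adjusted p = 0.0401), POLR2A lower, and AXL (0.17, adjusted p = 0.225) and KDM4C (0.10, adjusted p = 0.644) did not pass. PROS1, a TAM receptor ligand, was 1.12 higher (SE 0.216). MERTK, another TAM receptor, was 0.56 higher (adjusted p = 0.0425; centred −0.49, adjusted p = 0.288), a call that ended without any of 10 of the 16 libraries, over a range of 0.41 to 0.68. GAS6, a further ligand, did not pass (0.18, adjusted p = 0.643). The list was not called (adjusted p = 0.481).

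Without centring camera called 16 of 25 lists as higher in knockdown, but 2 when centred, and 1 when centred with an estimated correlation. Uncentred with an estimated correlation it called 10, namely m6A machinery, glycolysis and cytoskeleton, translation, cytoplasmic ribosomal proteins, respiratory chain, S phase, mitosis, interferon-stimulated genes, heat shock proteins and inflammatory cytokines. The other calls gave, with an estimated correlation, adjusted p = 0.0606 for mitochondrially encoded mRNAs, 0.0973 for cholesterol biosynthesis, 0.145 for ATF4 and unfolded protein response and 0.307 for the MLL-fusion programme. The snoRNA host genes gave adjusted p = 0.136 and long noncoding RNAs adjusted p = 0.0606 with an estimated correlation. The MLL-fusion call also ended without any of 7 of the 16 libraries, with adjusted p up to 0.0697, and that of long noncoding RNAs without knockdown 4.5 h replicate 2 (adjusted p = 0.0509). Every member counted past the threshold was higher, for example 76 of 79 ribosomal proteins (76 adjusted over the list alone), 55 of 55 respiratory chain genes (55) and 37 of 39 interferon-stimulated genes (37), of which 0 were higher and 8 lower when centred. When centred the interferon (adjusted p = 0.0715) and glycolysis (adjusted p = 0.560) lists turned lower without being called, and S phase turned lower at a CPM minimum of 20 (adjusted p = 0.792). They were also 19 of 21 m6A machinery genes (19), 23 of 23 glycolysis and cytoskeleton genes (23), 32 of 33 translation factors (32), 13 of 13 mitochondrially encoded mRNAs (13), 37 of 38 S phase genes (37) and 15 of 16 heat shock genes (15). The rest were 25 of 29 ATF4 and unfolded protein response genes (27), 17 of 22 MLL-fusion genes (17), 28 of 30 inflammatory genes (28), 20 of 22 snoRNA host genes (20) and 12 of 13 long noncoding RNAs (12). COX7A2, a cytochrome oxidase subunit, was 1.20 higher (SE 0.0356), MT-CO2, its mitochondrially encoded partner, 1.21 (SE 0.0404) and ISG15, a ubiquitin-like interferon target, 1.12 (SE 0.042). MEF2C, a transcription factor of the MLL-fusion list, was 1.30 higher (SE 0.0447) and CCL3, a chemokine, 1.38 (SE 0.0563).

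The 9 lists not called had adjusted p from 0.141 to 0.834. Members higher were 37 of 44 immediate early genes (38 adjusted over the list alone), 14 of 19 p53 targets (14) and 8 of 16 histones (7). They were also 27 of 38 monocyte and macrophage genes (28), 16 of 19 BCL2 family genes (18), 14 of 18 hypoxia targets (14), 42 of 50 zinc finger genes (44) and 3 of 5 lymphoid markers (3). APOC1, an apolipoprotein of macrophages, was 1.33 higher (SE 0.0698). Of the markers of other cell types, erythroid and kidney markers had 4 tested genes each, too few for a test, with CPM up to 7.30 and 2.88.

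The largest genotype effects were CHN1, a Rac-regulating chimaerin, at 2.89 log2 (SE 0.667), LINC01503, a long noncoding RNA, at 2.55, MOGS, a glucosidase of N-glycan processing, at 2.41, and TMEM9, a lysosomal membrane protein, at 2.39 (SE 0.313). DUS1L, a dihydrouridine synthase, was 2.29 higher, MVD of the mevalonate pathway 2.25, NECAP1, an endocytic adaptor, 2.23, SLC25A45, a mitochondrial carrier, 2.21, AKT2, a kinase, 2.19 and ZBED3-AS1 2.18. All but DUS1L and SLC25A45 were listed at 0 in 1 to 4 control libraries, and MIR497HG in 2 of knockdown, so the sizes and ranks depend on the pseudocount. TMEM9 (1.34, adjusted p = 0.0165), NECAP1 (1.18, adjusted p = 0.0218) and DUS1L (adjusted p = 0.0213) also passed when centred. NECAP1, ZBED3-AS1 and MIR497HG overlap another gene on the same strand, and MIR497HG also C17orf49 on the opposite one. Only 4 genes met the rule in the lower direction. PDE5A, a cGMP phosphodiesterase, was at −0.78 and MIR497HG, a microRNA host gene, at −0.74. KCNAB1, a potassium channel subunit, was at −0.73 and FERMT2, an integrin co-activator, at −0.51. FERMT2 rates in control did not fall over the chase, with 5.37% and 4.69% at 0 h and 8.05% and 5.48% at 7.5 h. In knockdown they were 5.32% and 4.45% at 0 h and 2.47% and 4.10% at 7.5 h. Rates of MIR497HG in knockdown were at most 0.0662%, close to the pseudocount. Whether these conversions came from label was not tested. The PDE5A call ended without any of 10 libraries (−0.93 to −0.62) and that of FERMT2 without any of 6 (−0.58 to −0.40).

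At single times the same shift appeared. At 0 h, 5778 genes were higher and 29 lower in knockdown by limma, with a median of 1.01 log2, and 8 were higher and 81 lower when centred. At 7.5 h, 5448 were higher and 50 lower, with a median of 0.92, and 65 and 114 when centred. The total at 0 h was 5807 and fell to 3777 without control 0 h replicate 1, 3331 without knockdown 0 h replicate 1 and 3414 without knockdown 0 h replicate 2, each of which left one library in its group, assumed to vary like the other groups.

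The slope in control asked how fast rates fell during the chase. CCL3 lost label quickly, from 1.02% ± 0.0572 at 0 h to 0.151% ± 0.00871 at 7.5 h (SD, n = 2), a slope of −0.33 log2 per hour (SE 0.0179) with a halving time of 3.04 h. ZFP36, a protein that destabilises mRNAs, fell faster at −0.42 (SE 0.0469), and MT-CO2 fell at −0.22 (SE 0.0136). The ribosomal protein mRNA RPS6 rose from 0.134% ± 0.0041 to 0.232% ± 0.00825, at 0.09 log2 per hour (SE 0.0145). By limma 5587 genes fell and 561 rose, with a median slope of −0.11 log2 per hour over all tested genes. Among those that fell the median halving time was 4.28 h. All halving times given are those of the rate plus the pseudocount, which makes them longer, more so at low rates. After centring 2852 genes rose and 1536 fell relative to the common fall.

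Immediate early and short-lived mRNAs had the lowest median slope of the 25 lists, −0.30 log2 per hour. Of the 44 tested 35 fell and 0 rose, and 39 fell adjusted over the list alone (camera adjusted p = 1.6e-08; adjusted p = 0.0439 with an estimated correlation). DUSP6, a phosphatase of MAP kinases, fell by 0.45, KLF6, a transcription factor, by 0.29 and ZFP36L2, a relative of ZFP36, by 0.31 log2 per hour. Of 30 inflammatory cytokine and NF-kB genes 21 fell, and 21 adjusted over the list alone (adjusted p = 2.7e-04; adjusted p = 0.0383 with an estimated correlation), with the chemokines CCL4 at −0.39 and CCL2 at −0.16 and the apoptosis inhibitor BIRC3 at −0.32. Of 21 m6A machinery genes 17 fell and 1 rose, and 17 and 1 adjusted over the list alone (adjusted p = 0.00148; adjusted p = 0.0383 with an estimated correlation). They held WTAP, of the methyltransferase complex, at −0.29, CBLL1, of the same complex, at −0.31, the reader YTHDF3 at −0.28 and the demethylase FTO at −0.25.

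Further lists were called as falling, but not with an estimated correlation. Of 22 MLL-fusion genes 17 fell, and 17 adjusted over the list alone (adjusted p = 3.5e-04; adjusted p = 0.142 with an estimated correlation), with ZEB2 at −0.31, PBX3 at −0.29 and MEF2C at −0.22, all transcription factors. Of 13 mitochondrially encoded mRNAs 12 fell, and 12 adjusted over the list alone (adjusted p = 8.5e-08; adjusted p = 0.115 with an estimated correlation), with MT-ND1, a subunit of complex I, at −0.22. Of 13 long noncoding RNAs 9 fell, and 9 adjusted over the list alone (adjusted p = 0.0231; adjusted p = 0.0616 with an estimated correlation), among them LINC-PINT at −0.46, MIR155HG at −0.42, NEAT1 at −0.23 and PVT1 at −0.21. Of 50 zinc finger genes 30 fell and 1 rose, and 31 and 1 adjusted over the list alone (adjusted p = 4.0e-04; adjusted p = 0.0969 with an estimated correlation), with ZNF254 at −0.45, ZNF92 at −0.36 and ZNF148 at −0.30.

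The groups with rising rates encode abundant housekeeping proteins. Of 55 respiratory chain genes 30 rose and 2 fell, and 32 and 2 adjusted over the list alone (camera adjusted p = 3.2e-17; adjusted p = 0.0383 with an estimated correlation), with COX5A, of cytochrome oxidase, at 0.12 and ATP5PO and ATP5MC1, of ATP synthase, at 0.09 and 0.10 log2 per hour. Of 79 ribosomal protein genes 22 rose and 1 fell, and 21 and 1 adjusted over the list alone (adjusted p = 8.8e-16; adjusted p = 0.00774 with an estimated correlation), with RPL18 at 0.13 and RPL27 at 0.08. Of 23 glycolysis and cytoskeleton genes 7 rose and 1 fell, and 9 and 4 adjusted over the list alone (adjusted p = 1.3e-06; adjusted p = 0.0463 with an estimated correlation). LDHB, lactate dehydrogenase, and GAPDH rose at 0.09, CFL1, cofilin, at 0.08 and TMSB10, a thymosin, at 0.07.

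Translation factors and monocyte genes moved both ways before centring. Of 33 translation factors 5 rose and 6 fell, the same numbers adjusted over the list alone, with a median slope of 0.01 and a mean of −0.01; camera called the list as higher than other genes (adjusted p = 0.00563; adjusted p = 0.118 with an estimated correlation). EIF4B, an initiation factor, fell at −0.25 and EIF3H, another, at −0.17. Of 38 monocyte and macrophage genes 4 rose and 7 fell, and 3 and 7 adjusted over the list alone, with a median of 0.02 and a mean of −0.02 (adjusted p = 0.0113; adjusted p = 0.0506 with an estimated correlation). The receptor TLR2 fell at −0.38, the transcription factor CEBPA at −0.30 and the proteoglycan VCAN at −0.18. Relative to the common fall, 23 translation factors rose and 1 fell, and 14 monocyte genes rose and 3 fell (26 and 3, and 15 and 4, adjusted over the list alone).

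Centring left fewer members of the falling lists past the threshold in control: 5 m6A machinery genes (6 adjusted over the list alone), 24 immediate early (26), 10 inflammatory (14), 8 MLL-fusion (8), 11 mitochondrially encoded (12), 3 long noncoding (4) and 11 zinc finger genes (11). Long noncoding RNAs were no longer called when centred (adjusted p = 0.160). The heat shock list, not called in the uncentred test of all libraries, was called as higher when centred (camera adjusted p = 0.00567, and 0.230 with an estimated correlation). Of its 16 members 9 were higher and 0 lower (10 and 1 adjusted over the list alone).

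The 13 other lists were not called, with adjusted p from 0.109 to 0.998. Members that fell were 20 of 39 interferon-stimulated genes (21 adjusted over the list alone), among them IFIT2 at −0.32 and IFIT3 at −0.27, 9 of 19 BCL2 family genes (10), among them XIAP at −0.32 and PMAIP1 at −0.32, and 7 of 19 p53 targets (7), among them TNFRSF10B at −0.33 and MDM2 at −0.22. They were also 11 of 29 ATF4 and unfolded protein response genes (11), with DDIT3 at −0.27 and ATF4 at −0.22, 19 of 38 S phase genes (20), 16 of 38 mitosis genes (17) and 5 of 16 histones (5). The remainder were 8 of 23 cholesterol biosynthesis genes (8), 3 of 16 heat shock genes (3), 8 of 18 hypoxia targets (8), 11 of 22 snoRNA host genes (11), 1 of 5 lymphoid markers (1) and 4 of 7 axis genes (4). Members that rose were 5 interferon-stimulated, 2 mitosis, 2 heat shock, 2 snoRNA host, 1 S phase, 1 ATF4 and 1 lymphoid gene, the same adjusted over the list alone, with 1 BCL2 family gene added. The heat shock list was called as higher than other genes without control 7.5 h replicate 2 (adjusted p = 0.0474). KDM4C fell at −0.18, MYB at −0.26, PROS1 at −0.31 and MERTK at −0.19, which did not pass without control 7.5 h replicate 1 (−0.12). AXL (−0.019, adjusted p = 0.474), POLR2A (−0.045, adjusted p = 0.520) and GAS6 (0.139, adjusted p = 0.130) did not pass, and AXL turned to 0.116 when centred (adjusted p = 2.2e-04). ALKBH5 fell at −0.26 (SE 0.0763, limma adjusted p = 0.0145), and did not pass without control 7.5 h replicate 1 (−0.20).

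**Figure D2:**
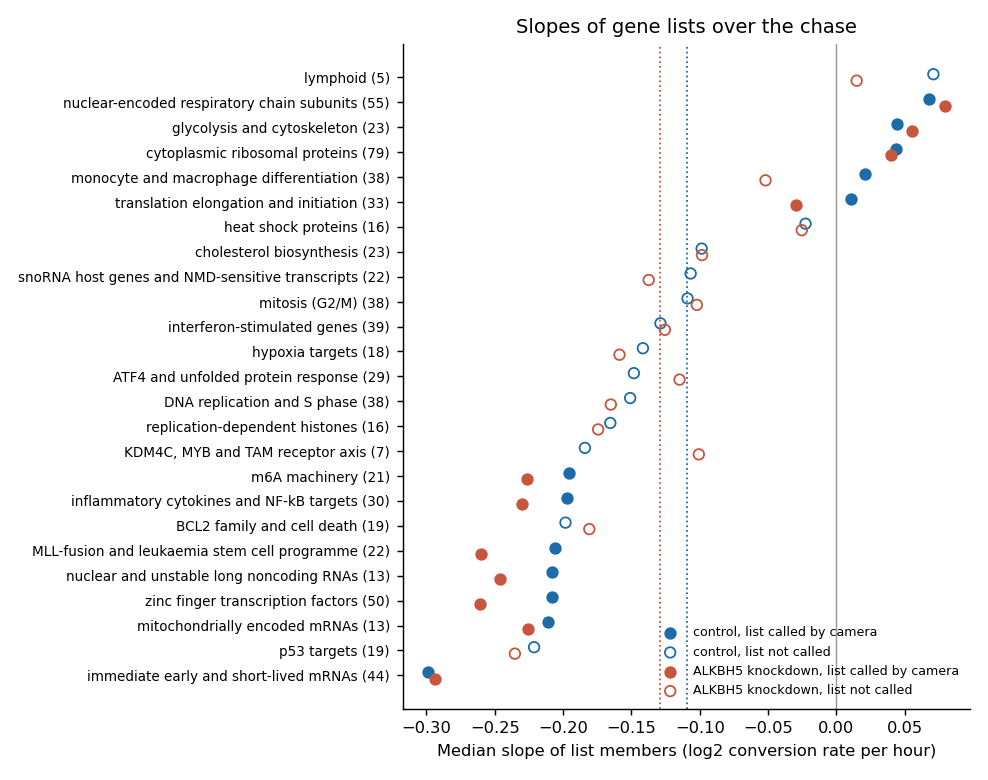
Median slope of the tested members of each gene list in log2 conversion rate per hour (horizontal axis), with the number of tested members after each name. Filled points are lists called by camera and open points lists not called; dotted lines mark the medians of all genes, −0.11 in control and −0.13 in knockdown. Respiratory chain and ribosomal protein lists lie above 0 and immediate early mRNAs lie near −0.30.

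The steepest falls in control were those of LINC02241 at −0.77 log2 per hour (SE 0.168), TNIP3, an NF-kB inhibitor, at −0.65, SPRY1, a signalling inhibitor, at −0.62, ATOSB at −0.59, NAT9 at −0.55, FHL1 at −0.54, TMEM105 at −0.53, GNAI1, a G protein subunit, at −0.52, PRLR, the prolactin receptor, at −0.52 and USP46, a deubiquitinase, at −0.51 (SE 0.0494). LINC02241, TNIP3, SPRY1, ATOSB, TMEM105 and PRLR were listed at 0 in both control libraries at 7.5 h, and NAT9, FHL1 and USP46 in 1, so the size of these slopes depends on the pseudocount. The steepest rises were IFTAP at 0.37, TTN at 0.30, TMEM256 at 0.30 and ARF5, a small GTPase, at 0.29. IFTAP was listed at 0 in both control libraries at 0 h, and TMEM256 and ARF5 in 1, so these rises depend on it too. TMEM256 and ARF5 overlap another gene on the same strand. The SPRY1 call ended without any of 6 libraries and the IFTAP call without any of 3, over ranges of −0.72 to −0.56 and 0.27 to 0.48. FHL1 (−0.45) did not pass without control 7.5 h replicate 1. Without the 0 h libraries 2924 genes fell and 150 rose.

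The slope in knockdown asked the same of the ALKBH5 knockdown cells. CCL3 fell from 2.55% ± 0.0902 at 0 h to 0.517% ± 0.0194 at 7.5 h (SD, n = 2), at −0.30 log2 per hour (SE 0.0179). MCL1, an apoptosis inhibitor, fell at −0.37 (SE 0.0324) and MT-CO2 at −0.24 (SE 0.0136), while COX5A rose at 0.14 (SE 0.0167) and RPL27 at 0.11 (SE 0.0149). By limma 6151 genes fell and 659 rose, with a median slope of −0.13 log2 per hour over all tested genes. Among those that fell the median halving time was 4.14 h. After centring 2867 rose and 1400 fell relative to the common fall.

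Immediate early mRNAs fell in 36 of 44 cases, and 39 adjusted over the list alone (camera adjusted p = 6.2e-07; adjusted p = 0.0629 with an estimated correlation), with ZFP36 at −0.45 and KLF6 at −0.28. Inflammatory genes fell in 23 of 30, and 23 adjusted over the list alone (adjusted p = 2.6e-04; adjusted p = 0.0277 with an estimated correlation), with TNFAIP8 at −0.34 and CCL2 at −0.21. In the m6A machinery 17 of 21 fell and 1 rose, and 18 and 1 adjusted over the list alone (adjusted p = 0.00153; adjusted p = 0.0277 with an estimated correlation), with YTHDF3 at −0.32, WTAP at −0.27 and FTO at −0.26. MLL-fusion genes fell in 17 of 22, and 18 adjusted over the list alone (adjusted p = 2.5e-05; adjusted p = 0.0966 with an estimated correlation), with ZEB2 at −0.32, PBX3 at −0.26, CDK6, a cell cycle kinase, at −0.26 and MEF2C at −0.24. Mitochondrially encoded mRNAs fell in 13 of 13, also 13 adjusted over the list alone (adjusted p = 2.6e-08; adjusted p = 0.0966 with an estimated correlation), with MT-ND1 at −0.26. Long noncoding RNAs fell in 9 of 13, also 9 adjusted over the list alone (adjusted p = 0.0201; adjusted p = 0.0629 with an estimated correlation), with MIR155HG at −0.45, PVT1 at −0.29 and NEAT1 at −0.25. Zinc finger genes fell in 34 of 50, and 36 adjusted over the list alone (adjusted p = 2.3e-04; adjusted p = 0.0902 with an estimated correlation), with ZNF217 at −0.34, ZNF148 at −0.27 and ZNF131 at −0.25.

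Respiratory chain genes rose in 37 of 55 cases and fell in 5, the same numbers adjusted over the list alone (camera adjusted p = 2.0e-20; adjusted p = 0.0277 with an estimated correlation), with NDUFA13 at 0.13 and COX7A2 at 0.09. Ribosomal protein genes rose in 28 of 79 and fell in 2, the same numbers adjusted over the list alone (adjusted p = 1.2e-14; adjusted p = 0.0107 with an estimated correlation), with RPL36 at 0.11 and RPL5 at 0.09. Glycolysis and cytoskeleton genes rose in 11 of 23 and fell in 2, also the same adjusted over the list alone (adjusted p = 3.4e-08; adjusted p = 0.0277 with an estimated correlation), with TMSB10 at 0.10 and ACTB, actin, at 0.10. PKM, pyruvate kinase, fell at −0.11, which turned to 0.040 when centred (adjusted p = 0.113). Translation factors rose in 5 of 33 and fell in 8, the same numbers adjusted over the list alone, with a median slope of −0.030; camera called the list as higher than other genes (adjusted p = 0.0338; adjusted p = 0.252 with an estimated correlation), a call that ended without either knockdown 0 h library (adjusted p up to 0.0813). EIF4E, the cap-binding factor, fell at −0.31 and EIF4B at −0.30.

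The 14 other lists had adjusted p from 0.157 to 0.974. Members that fell were 23 of 39 interferon-stimulated genes (24 adjusted over the list alone), 9 of 19 p53 targets (9), 17 of 38 S phase genes (17), 15 of 38 mitosis genes (15) and 5 of 16 histones (4). They were also 12 of 29 ATF4 genes (12), 10 of 19 BCL2 family genes (10), 12 of 22 snoRNA host genes (12), 8 of 18 hypoxia targets (8), 8 of 23 cholesterol biosynthesis genes (8), 10 of 38 monocyte genes (10), 5 of 16 heat shock genes (5), 1 of 5 lymphoid markers (1) and 4 of 7 axis genes (4). Members that rose were 5 interferon-stimulated (7 adjusted over the list alone), 4 monocyte (4), 3 heat shock (4), 1 mitosis (1), 1 cholesterol biosynthesis (1), 1 BCL2 family (1), 1 lymphoid (1) and 0 snoRNA host genes (2).

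Centring left 5 m6A machinery genes falling in knockdown (5 adjusted over the list alone), 14 immediate early (17), 10 inflammatory (10), 11 MLL-fusion (12), 11 mitochondrially encoded (11), 4 long noncoding (6) and 11 zinc finger genes (11). It ended the call of long noncoding RNAs (adjusted p = 0.115) and called heat shock genes as higher (adjusted p = 0.0120; adjusted p = 0.289 with an estimated correlation). Relative to the common fall, 20 translation factors rose and 2 fell (22 and 2 adjusted over the list alone).

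In the axis list KDM4C fell at −0.19, MYB at −0.21, PROS1 at −0.29 and AXL at −0.071 (SE 0.0194, limma adjusted p = 0.00764), which turned to 0.079 when centred (adjusted p = 0.00447). MERTK (−0.092, adjusted p = 0.186), GAS6 (−0.101, adjusted p = 0.265) and POLR2A (−0.003, adjusted p = 0.970; centred 0.147, adjusted p = 0.0410) did not pass. ALKBH5 fell at −0.54 (SE 0.0763, limma adjusted p = 4.3e-05). The steepest falls were TRHDE-AS1 at −0.74, ZNF133 at −0.63, EPM2A at −0.55, L3MBTL1, a chromatin protein, at −0.54, RUNX1T1 at −0.53, ZNF682 at −0.51, ERVK13-1 at −0.47, ZNF576 at −0.47, COG2 at −0.46 and BCL2L11, a pro-apoptotic protein, at −0.46. The steepest rises were ACD, a telomere protein, at 0.40, FAM50A at 0.33, CAPN12 at 0.28, EGFL7 at 0.27 and SERHL, a pseudogene, at 0.25. TRHDE-AS1 was listed at 0 in both knockdown libraries at 7.5 h and ZNF133 and RUNX1T1 in 1, and ACD, CAPN12 and EGFL7 in 1 at 0 h, so their slopes depend on the pseudocount. The ACD call ended without any of 3 libraries (0.24 to 0.52), the CAPN12 call without any of 5 (0.22 to 0.31) and the SERHL call without any of 2 (0.17 to 0.30). RUNX1T1 (−0.45) and ZNF576 (−0.40), which overlaps SRRM5 on the same strand, did not pass without knockdown 7.5 h replicate 1, nor did EGFL7 without knockdown 0 h replicate 1 (0.19). Without the 0 h libraries 3863 genes fell and 144 rose.

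**Figure D3:**
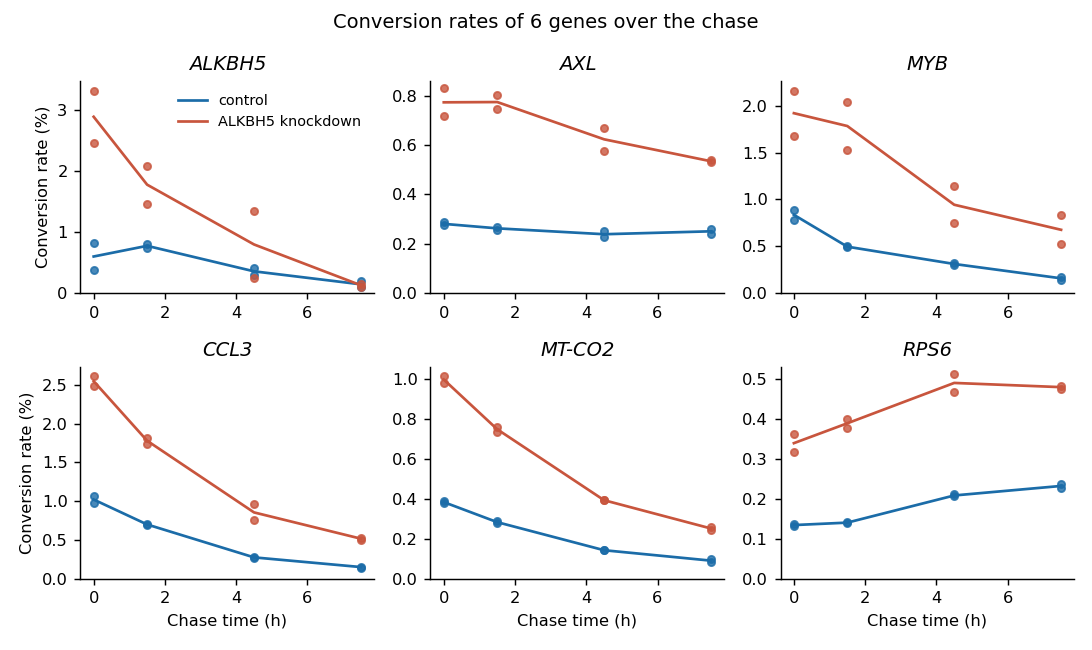
Conversion rates in percent (vertical axes) of 6 genes against chase time in hours (horizontal axes). Points are single libraries and lines join the means of the 2 replicates; CCL3 and MT-CO2 fell in both genotypes while RPS6 rose from 0.134% to 0.232% in control.

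The slope difference asked whether label was lost faster or slower in the knockdown. No gene passed the threshold, so the slope of KDM4C (slope difference −0.004, SE 0.0392), MYB (0.055, SE 0.0403), AXL (−0.052, SE 0.0274) and PROS1 (0.019, SE 0.0794) was not shown to differ between genotypes. MERTK differed by 0.099 (SE 0.0765), POLR2A by 0.042 (SE 0.0697) and GAS6 by −0.240 (SE 0.0985, unadjusted p = 0.0269, limma adjusted p = 0.578). ALKBH5 itself differed by −0.28 (SE 0.108, limma adjusted p = 0.544). The smallest p in the higher direction belonged to MYSM1, a histone deubiquitinase, at 0.26, NOL8, a nucleolar protein, at 0.22 and MAN2B2, a mannosidase, at 0.29 (adjusted p = 0.244, 0.256 and 0.256). In the lower direction it belonged to ZNF600 at −0.30, GANAB, a glucosidase of the endoplasmic reticulum, at −0.24 and AIG1 at −0.20 (adjusted p = 0.244, 0.278 and 0.278).

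By limma 0 of 16241 genes passed and 1269 had an unadjusted p under 0.05; after centring these were 0 and 1265. None of the 25 lists was called, the smallest adjusted p being 0.570, and 0 were called with an estimated correlation or by fry. A pseudocount of 1 percentage point, above most rates, called 239 genes (14 higher, 225 lower) and 9 lists. A pseudocount flattens falls on the log2 scale more at the lower control rates, which makes slope differences of falling genes lower. To a lesser degree this holds for the pseudocount of 0.05 too. The median rate at 7.5 h was 46.0% of that at 0 h in control and 45.1% in knockdown. Adjusted over the list alone, 1 S phase and 1 cholesterol biosynthesis gene had a higher slope in knockdown. The median SE was 0.0591 log2 per hour for genes at or above the median CPM and 0.145 below it, and simulated differences of 0.1 and 0.2 were recovered in 2.99% and 25.4% of cases at or above the median CPM, so most differences of that size would be missed. Across genes at or above the median CPM, which are not independent replicates, the slopes of the 2 genotypes had Pearson's r = 0.790 and Spearman's rho = 0.815, and across all tested genes 0.518 and 0.607. Of all tested genes 4473 fell in both genotypes, where independent lists would share 2116, and 313 rose in both, where they would share 22.8. Another 3 genes moved in opposite directions. Both slopes of a gene used the same variance estimate, which alone raises the number of shared calls. The excess over independent lists is therefore no test of agreement between genotypes.

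**Figure D4:**
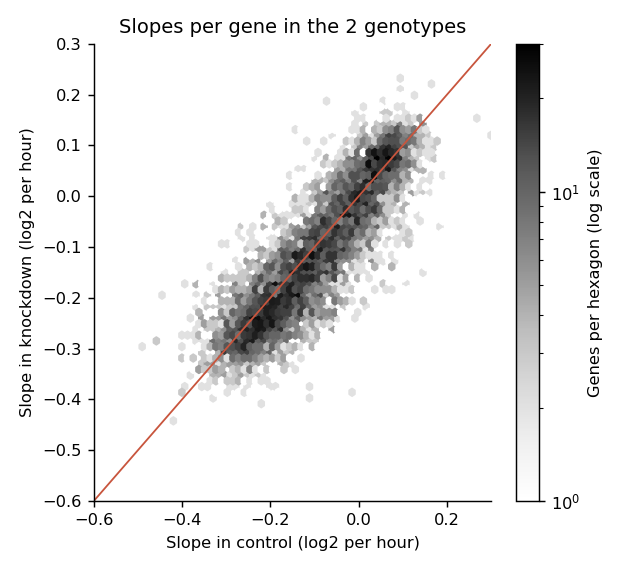
Slope in knockdown (vertical axis) against slope in control (horizontal axis), both in log2 conversion rate per hour, for the 8126 genes at or above the median CPM. Shading counts genes per hexagon on a log scale, the line marks equal slopes, and 18 genes lie outside the plotted range; Pearson's r was 0.790 for these genes and 0.518 for all tested genes.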

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

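The tests of faster turnover, of entry after the wash, of background in later libraries, of faster ALKBH5 loss, and the splits of slope calls were chosen only after the result was seen.

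ALKBH5 fell by 0.54 log2 per hour in knockdown and by 0.26 in control, a slope difference of −0.280 (SE 0.108, unadjusted p = 0.0195). Noise of a gene this weakly covered may account for it: 90.4% of the 500 genes nearest in CPM had a slope difference smaller in size. Faster loss of ALKBH5 RNA in the knockdown cannot be told apart from that noise. The rule used for it needed the limma adjusted p over all genes to pass, and that was 0.544. This adjustment makes no allowance for ALKBH5 having been named beforehand. The slope difference stayed between −0.333 and −0.216 without any 1 library. Of the same 500 genes, 0.6% had a more negative knockdown slope. Rates do not show whether ALKBH5 RNA was reduced.

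Rates in knockdown were 2.16, 2.30, 2.30 and 2.11 times those in control at 0, 1.5, 4.5 and 7.5 h. An added background of mismatches is argued against, since the difference at 0 h was 5.70 times as large in the fifth of genes with the highest control rates at 1.5 h as in the lowest. Generally faster turnover is argued against as the whole cause, since the median knockdown slope was 1.19 times that of control. A single labelling or conversion factor could account for the shift: the ratios in the lowest and the highest of these groups, 2.27 and 2.11, differed by 1.08 times. That factor goes with the genotype in every library, and whether it arose in the cells or in the chemistry was not tested.

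Rates of 313 genes rose in both genotypes. Late entry of RNA from long genes is argued against, since their median span was 0.179 times that of genes matched on CPM (6631 against 36994 bases). A higher background in later libraries is argued against, since the lowest 1% of rates among abundant genes changed by −0.0062 percentage points in control and −0.0042 in knockdown. Entry of RNA labelled in the pulse shortly after the wash stays open, because the answer depends on the scale. The change per hour from 4.5 to 7.5 h was at most 0.222 of that from 0 to 1.5 h in log2, but 0.617 in control and 0.269 in knockdown in percentage points of the median rate.

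RDM1 passed the limma F test on 3 interaction terms of genotype and time (adjusted p = 0.00218). Its rates were 0.787% and 0.548% in control at 4.5 h. In knockdown they were 1.92%, 1.44%, 1.73% and 2.42% at 0 and 1.5 h. All others were listed at 0, so most groups had no spread between replicates, which lowers the variance behind this p-value. Its CPM of 1.93 lay near the minimum of 1. A difference between genotypes cannot be told apart from conversions missed at low depth.

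Genotype labels were exchanged within each time in 100 of 648 possible splits, the real one included. The real split called 11325 genes by genotype against at most 6818 in other splits (1 of 100 splits as large, the real one). It called 16 lists against 10 (1 of 100). The shift in every knockdown library favours the real split in these uncentred counts, so they decide little. After centring it called 982 genes against 1 (1 of 100), which argues against a random grouping of these libraries. The splits cannot exclude differences between single cultures, since the labels do not say that replicates were separate cultures. For the 1265 genes at unadjusted p under 0.05 in the centred slope difference, 14 of 100 splits gave as many, up to 2438. The splits do not exclude chance for these genes, but they decide little. Centring leaves genotype effects of single genes in place, and other splits mix these into the slopes. For the genes called in the slope difference the splits decide nothing: the real count was 0, which all 100 splits reach by construction. Other splits called up to 8698, because they mix the genotype shift into the slopes.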

How the results depend on the processing

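The tests with libraries centred, CPM minimums of 5 and 20, a pseudocount of 0.01, no variance trend, a subtracted background and without the 0 h libraries were chosen after the data were seen; the others were planned. Where no reason is given below, the cause was not tested.

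Centring ended most genotype calls, leaving 982 genes (461 shared with the uncentred calls), 89 at 0 h and 179 at 7.5 h, and changed the knockdown slope calls to 4267. A CPM minimum of 20 left fewer genes to test, with 5164 by genotype, 3061 for the control slope and 3435 for the knockdown slope. Without the 0 h libraries the slopes called 3074 genes in control and 4007 in knockdown. For the slope difference a pseudocount of 1 gave 239 genes (14 higher, 225 lower). That pseudocount lies above most rates and flattens falls more at the lower control rates. No variance trend gave 1 gene by limma, C6orf163 (−0.54, adjusted p = 0.0353). The F test gave 2, with 1161 at unadjusted p under 0.05. ALKBH5 stayed at 0.99 with no filter (adjusted p = 0.0530) and with no time term (0.99, adjusted p = 0.186), was 0.57 without the 0 h libraries (adjusted p = 0.222), turned to −0.061 when centred and was not tested at CPM minimums of 5 and 20.

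Leaving out each library gave 10873 to 11280 genes by genotype, 5200 to 6133 for the control slope, 5644 to 7055 for the knockdown slope, 0 to 2 for the slope difference, 3331 to 6430 at 0 h and 3671 to 5563 at 7.5 h. The 2 genes, GNAO1 (−1.15) and MAPK12 (−0.80), appeared without control 7.5 h replicate 2. ALKBH5 ranged from 0.78 to 1.22. Lists numbered 14 to 16 by genotype, 12 to 13 and 10 to 11 for the control and knockdown slopes, and 0 to 0 for the slope difference.

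Lists called by genotype were 2 when centred, 1 when centred with an estimated correlation, 8 and 2 at CPM minimums of 5 and 20, 10 with an estimated correlation and 25 by fry. For the control slope they were 6 with an estimated correlation and 22 by fry, for the knockdown slope 5 and 23, and for the slope difference 9 at a pseudocount of 1. With no filter, 18 list results over all comparisons newly passed, 3 no longer passed, 1 reversed and 78 stayed the same.

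Centring reversed the genotype effects of POLR2A (−0.77), MERTK (−0.49), SREBF2 (−0.052), MALAT1 (−0.30), LYZ (−0.57), IFITM1 (−0.32), CCL5 (−0.31) and TMSB4X (−0.31), and the slopes of AXL (0.12 in control, 0.079 in knockdown), POLR2A (0.15) and PKM (0.040) in knockdown, by removing the common shift. It reversed the genotype direction of the glycolysis list (adjusted p = 0.560, and 0.641 with an estimated correlation) and the interferon list (0.0715 and 0.197). The S phase list reversed at a CPM minimum of 20 (0.792) and the monocyte list with no filter (0.0040). By fry, which compares a list with 0 and not with other genes, directions by genotype reversed for histones (4.3e-07), monocyte genes (1.1e-10), hypoxia targets (6.8e-11) and lymphoid markers (1.4e-04). They also reversed for translation (0.170) and monocyte genes (0.00528) in the control slope, and for translation (0.00724), cholesterol biosynthesis (1.8e-05) and monocyte genes (2.3e-05) in the knockdown slope. Immediate early genes reversed in the slope difference at a pseudocount of 1 (0.0319).

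Of 2290 values of named genes under alternatives other than leaving out a library, 2191 kept their direction and side of the threshold, 82 no longer passed, 5 newly passed and 12 reversed; of 2976 without a library, 2920 kept them. Of 1284 list results 1121 kept them, 89 no longer passed, 58 newly passed and 16 reversed.

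With the replicate number as a block the counts were 11319 by genotype, 6076 and 6772 for the control and knockdown slopes, 0 for the slope difference, 5652 at 0 h and 5390 at 7.5 h, with 16, 12, 11 and 0 lists, so no count moved by over 1.5 times. Deviations of same-numbered replicates in this pairing correlated by 0.00965 on average over 28 pairs of groups, from −0.0211 to 0.0492.

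RLE and library size scaling, DESeq2, other denominators of labelled reads and library size scaling of the list tests were not run, because the table holds rates. The list tests used variances without the trend in CPM, and list tests with that trend were not run. The unknown depth limits all of these values, and genes below the median CPM had a median SE of 0.145 log2 per hour in the slope difference.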

Other observations

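The 2 DRACH motif tests, their sizes and their bounds were chosen before the result was seen, but the way they were judged changed afterwards. On the first run the correlation over whole transcripts was judged to argue against the hypothesis, because it lies closer to 0 than the bound of −0.05. After that value was seen, its spread was counted against the bound, which moved the verdict to open, and the number of permutations was raised to 100000.

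DRACH motifs, the sequence context in which m6A is placed, were set against the slopes across genes at or above the median CPM, which are not independent replicates. Transcripts with more motifs per kilobase fell faster in both genotypes, with Spearman's rho = −0.148 for the control slope and −0.163 for the knockdown slope.

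The hypothesis was that mRNAs with more m6A motifs fall faster in the knockdown, which needed a correlation with the slope difference under −0.1. Over 7086 genes Spearman's rho was −0.0467 (spread 0.0119) and Pearson's r −0.0410 (permutation p = 7e-05, adjusted p = 0.00014 over the 2 tests). The size set beforehand was missed, so the hypothesis was not met; by the first rule it is argued against and by the changed rule it is open. The median slope difference was −0.0012 log2 per hour in the fifth of genes with the fewest motifs and −0.0157 in the fifth with the most. For motifs in the 3′ UTR over 6443 genes rho was −0.0163 (permutation p = 0.2, adjusted p = 0.2). Either rule judged this against the hypothesis for that region. Noise in the slope differences (median SE 0.0591 log2 per hour) weakens any such correlation, and the bounds made no allowance for it. Neither correlation therefore excludes a link between motifs and the slope difference.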
